A study of Mus musculus with 4 samples.

How the data were processed

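Liver RNA was amplified and hybridised to AceGene Mouse Oligo Chip 30K arrays, with the diet sample in Cy5 and the chow reference in Cy3, per the labels and the series' design text. Slides were scanned on an Agilent G2505B scanner, spots were read with GenePix Pro 4.1 and values were LOWESS-normalized in GeneSpring 7.2, per the design text. LOWESS removes intensity-dependent dye differences within an array, but not a dye preference of a single probe. Background correction and spot filters are not given in the sources used here. The deposited values are signed log ratios, read as log10 of diet over chow. The base is an inference: read as base 2, the interquartile range on the atherogenic 6-week array would correspond to a 13.5% difference in ratio, and read as base 10 to 52.4%. Direction was taken from the dyes in the labels and is not stated for the values. Centring beyond LOWESS is unknown. The median deposited values were -0.019, 0.006, -0.005 and 0.006 on the atherogenic 6-week, atherogenic high-fat 6-week, atherogenic 24-week and atherogenic high-fat 24-week arrays. Adjusted p-values do not depend on the base, while folds and counts by fold do. No spot intensities were used here, so random gene lists were not matched on expression.

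Values were converted to log2 and used as deposited. Probes with a missing value on any array were left out (975 of 28845). The planned filter, a value above 0, does not apply to signed ratios and became a filter on missing values. Of all probes, 17637 had 1 gene symbol in the platform annotation, 64 had several and 11144 were not listed and stay unnamed here. Symbols were updated through their gene identifiers to the RefSeq table of GRCm38.p6, which did not match 252 probes with 1 symbol. No coordinates are given, since no build is named for the arrays. A gene's value is the mean of its probes; 2718 genes had more than 1 probe, and probes of a gene differed on an array with a pooled SD between 0.33 and 0.47 (log2).

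Tests used limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg) in R 4.3.3. Diet over chow was the mean of the 4 arrays against 0, with 3 residual degrees of freedom. High fat and duration were terms of an additive model with 1 residual degree of freedom, the interaction of both, moderated across probes. Each condition had 1 array, so p-values measure the spread between 4 conditions, not between animals, and the interaction itself could not be tested. If arrays shared a chow sample, which is not known here, the p-values also leave out the spread between chow samples. Gene lists (31 with at least 5 measured genes) were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, with which no list passed in any comparison (smallest adjusted p = 0.212 for diet over chow, 0.756 for high fat and 0.752 for duration). The correlation is estimated from 3 or 1 residual degrees of freedom, and the test that uses it rests on as few. For high fat the xenobiotic list had an estimated correlation of 0.00488, below the preset 0.01. Its adjusted p still went from 7.44e-07 to 0.756. Other lists lay above the preset, such as MHC class II for diet over chow (0.542). Calls that ended therefore do not measure correlation between genes alone, and this form of the test cannot decide whether a list changed. On single arrays a list's median was set among 10000 random lists of its size.

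The groups, tests, gene lists and naming rule were fixed before the data were examined. Named were the 10 largest rises and falls past the threshold with 1 sign on all arrays; 8 genes in each direction for high fat and duration, by size past the threshold or, where too few passed, by the smaller of both within-pair differences; up to 4 members per list past the threshold for diet over chow, or 2 as values; and a fixed set of genes of sterol, lipid, redox, inflammatory and fibrosis biology. Part of that set is not reported here. Predicted and unnamed genes were passed over. Alternatives were centring, scaling, gene means, limits on extreme ratios, robust eBayes, other thresholds and models, and leaving out each array. Chosen after seeing the data were centring by probe position, removal of probes at repeated values, and other log bases.

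The tests were tested on simulated data with the spread of the arrays, with 200 of 27870 probes changed. For diet over chow 88 of 100 changes of 1 log2 unit and 98 of 100 changes of 2 units were recovered, with 7 false calls. For high fat 46 and 99 were recovered with 5 false calls, and for duration 66 and 100 with 14. The simulated noise was independent between probes and arrays, without shared chow, dye bias or processing that differed between diets. These false calls therefore give no rate for the real calls. On unchanged genes, drawn independently of each other and tested for diet over chow only, 0 of 31 lists were called. This run holds no correlation between genes, so it cannot show that the preset correlation limits false list calls.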

Results

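Liver RNA of male C57Bl/6J mice, an inbred laboratory strain, was measured on 4 two-colour oligonucleotide arrays. The mice had eaten an atherogenic diet, or an atherogenic diet with high fat, for 6 or 24 weeks. Each array set the liver RNA of 1 diet and duration, labelled with Cy5, against liver RNA of chow-fed mice, labelled with Cy3. There was 1 array for each of the 4 conditions and no dye-swapped array, so no single condition has a replicate error. The labels give chow for 6 or 24 weeks to match, except on the atherogenic 6-week array, where no duration of chow is given. The composition of the diets, whether arrays shared a chow sample, and whether an RNA came from 1 mouse or a pool, are not given in the sources used here. Of 28845 probes, between 27951 and 28806 had a value on an array, and 27870 had a value on all 4. Of these, 16994 named 1 mouse gene, 13544 genes in all. Ratios are log2 values of diet over chow. Folds and counts by fold rest on reading the deposited values as base 10 logarithms, an inference from their spread, since the base is not stated. Median log2 ratios lay between -0.06 and 0.02 on the 4 arrays. The SD across probes was 0.53 and 0.46 on the atherogenic 6-week and 24-week arrays. It was narrower on the high-fat arrays, at 0.37 and 0.39. The number of arrays limits the precision of every value.

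The first comparison asks which liver transcripts differed from chow across both diets and both durations. The metalloproteinase Mmp7 had the largest mean log2 ratio, 2.94 ± 0.22 (limma SE, 4 arrays; adjusted p = 0.00192), a 7.69-fold rise. The neutrophil proteins S100a9 and S100a8 rose by 2.70 ± 0.29 and 2.34 ± 0.25, and Lcn2, which binds bacterial iron carriers, by 2.22 ± 0.14. The chemokine Ccl6 rose by 2.47 ± 0.14, the lysosomal protease Ctss by 2.32 ± 0.17, and lysozyme Lyz1 by 2.22 ± 0.08, with Lyz1 between 2.09 and 2.35 on the 4 arrays. Ly6d, the antigen-presenting molecule H2-Aa and the fungal receptor Clec7a completed the 10 largest rises, at 2.38, 2.29 and 2.19.

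Among the 10 largest falls, Cyp8b1, the sterol 12-alpha hydroxylase of bile acid synthesis, fell by 3.07 ± 0.35 on the log2 scale (adjusted p = 0.0059). The fatty acid elongase Elovl3 fell by 2.70 ± 0.17. The largest fall of all belonged to Olfr874, an odorant receptor gene, at -3.74 ± 0.28. The hair keratin-associated gene Krtap17-1 and the vomeronasal receptor Vmn1r179 stood at -2.86 and -2.45, beside Thy1 (-2.98), Calcb (-2.51), Ammecr1 (-2.49), Btbd11 (-2.38) and Man2b1 (-2.17).

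**Figure D1:**
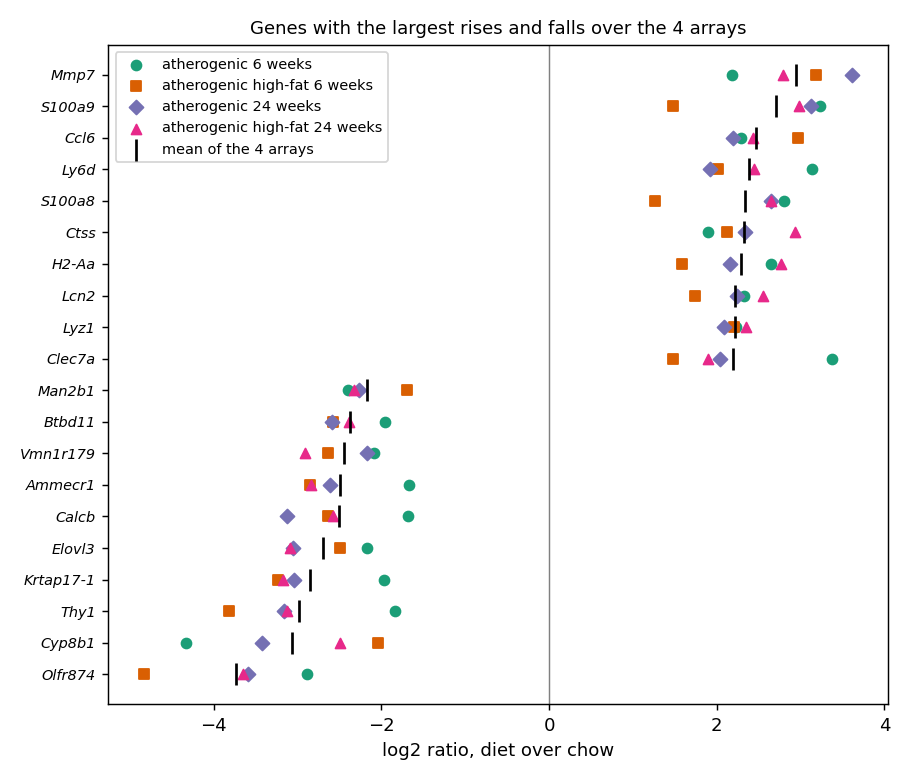
Log2 ratio of diet over chow (horizontal axis) for the 10 genes with the largest rise and the 10 with the largest fall, with a point for each array and a bar for the mean of the 4 arrays. Mean values run from -3.74 for Olfr874 to 2.94 for Mmp7; the genes were chosen to have 1 sign on all 4 arrays.

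Over all probes, 2880 passed an adjusted p of 0.05 in limma, 1484 higher and 1396 lower than chow. An unadjusted p under 0.05 was found for 7923, where independent arrays without change would give 1394. That number, like the p-values, assumes that arrays shared no chow sample, which is not known here. At the gene level 1634 genes passed, 849 higher and 785 lower. The count moved to 689, 1516 and 1856 probes without the atherogenic 24-week, the atherogenic high-fat 24-week and the atherogenic high-fat 6-week array. It rose to 10181 with diet and duration terms and to 9213 with duration as a random block. Arrays of the same diet were more alike (Pearson r across probes 0.73 and 0.83) than those of the same duration (0.39 and 0.57). None of these fits allowed for an error shared by arrays of the same diet. With such an error the p-values would be too small. The higher counts therefore do not show that 2880 is a cautious count. Of the 156 genes named by the rule, 120 passed for diet over chow, many of them named because they passed. Without the atherogenic 24-week array 69 lost that call, and without the atherogenic 6-week array 20. Without the atherogenic high-fat 6-week array 27 lost it, and without the atherogenic high-fat 24-week array 25. Every array carried diet in Cy5, so a bias of a probe toward a dye cannot be told apart from a change by diet here.

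Lists of genes fixed in advance were tested next; members not counted as risen or fallen did not pass. Vsig4, Crp, Slco1a4, Rsad2, Mx2 and Stat2 were chosen after their values were seen. Macrophage markers were higher as a list (camera adjusted p = 1.06e-10; adjusted p = 0.482 with an estimated correlation). Of 32 measured members 17 rose and 1, Vsig4 (-1.33), fell; adjusted over the list alone, 21 rose and 1 fell. Besides Ctss and Lyz1, the tetraspanin Cd9 rose by 1.75 ± 0.19, the complement subunit C1qb by 1.74 ± 0.17, and Cd68 by 0.83 ± 0.09. MHC class II genes, which present antigen, were also higher (adjusted p = 2.51e-06; adjusted p = 0.518 with an estimated correlation). Of 10 measured, 6 rose, and 8 adjusted over the list alone, with H2-Eb1 at 1.69, H2-Ab1 at 1.41 and H2-DMb1 at 1.30. The probes of H2-Ab1 disagreed, from -0.22 to 2.17. Inflammation and chemokine genes followed (adjusted p = 3.44e-06; adjusted p = 0.482 with an estimated correlation). Of 37 measured, 12 rose and none fell; adjusted over the list alone, 18 rose and 1 fell. Ccl9 rose by 1.73, Ccl5 by 1.48, the adhesion molecule Vcam1 by 1.25 and the monocyte chemokine Ccl2 by 1.01 ± 0.25. Tnf, at 0.33 ± 0.26, did not pass (adjusted p = 0.438).

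Interferon response genes were higher (adjusted p = 0.0149; adjusted p = 0.543 with an estimated correlation), with 6 of 25 up, led by Ifi27l2a at 1.52, and 3 down, Rsad2 (-0.47), Mx2 (-0.45) and Stat2 (-0.36); adjusted over the list alone, 7 rose and 4 fell. Acute phase genes (adjusted p = 0.0423; adjusted p = 0.543 with an estimated correlation) had 6 of 24 up and Crp down (-0.56), and 8 up and 1 down adjusted over the list alone. Saa3 rose by 1.66 and Saa2 by 1.53, while Saa1, a close copy, stood at -0.09 ± 0.10. Neutrophil markers (adjusted p = 0.041; adjusted p = 0.543 with an estimated correlation) had 3 of 12 up and the elastase Elane down, with 3 up and 2 down adjusted over the list alone. Lymphocyte and natural killer markers (adjusted p = 0.0456; adjusted p = 0.543 with an estimated correlation) had 4 of 22 up, led by Cd53 at 1.33 and Cd48 at 0.95, and 8 up and 2 down adjusted over the list alone. The interferon list median was 0.55 and 0.38 on the plain arrays (6 and 24 weeks) and 0.15 and 0 on the high-fat arrays. The neutrophil median was 0.54 and 0.76 on the plain arrays and 0.02 and 0.09 on the high-fat arrays. With camera on ranks the acute phase, neutrophil and lymphocyte calls ended (adjusted p = 0.0717 each). The acute phase call also ended without the atherogenic 24-week (0.0889) or atherogenic high-fat 24-week array (0.102), the lymphocyte call without the atherogenic 6-week array (0.0598), and the neutrophil call without the atherogenic 6-week (0.0598) or atherogenic 24-week array (0.0889) or without probes at repeated values (0.0502).

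Extracellular matrix and fibrosis genes were higher (adjusted p = 1.25e-06; adjusted p = 0.543 with an estimated correlation), with 14 of 51 up and none down, and 18 up adjusted over the list alone. The fibrillar collagen gene Col1a2 rose by 1.75 ± 0.25, Col5a2 by 1.68 ± 0.21, Sparc by 1.18 ± 0.17 and Col3a1 by 1.03 ± 0.14, although the 3 probes of Col3a1 ranged from -0.22 to 2.36. Col1a1, the mean of 5 probes, rose by 0.58 ± 0.09, and the protease inhibitor Timp1 by 0.50 ± 0.09. Tgfb1, at 0.50 ± 0.19, and the myofibroblast actin Acta2, at 0.12 ± 0.11, did not pass. Bile duct cell markers were higher too (adjusted p = 0.00844; adjusted p = 0.543 with an estimated correlation): 4 of 14 rose, 6 adjusted over the list alone, with Tspan8 at 2.19, Anxa5 at 1.32, Bicc1 at 1.11 and Krt23 at 0.92. Stellate cell markers were not called as a list (adjusted p = 0.371): 4 of 21 rose, led by Vim at 1.41 ± 0.14, and 2 fell, with 6 up and 2 down adjusted over the list alone.

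Sterol handling split by direction. Cholesterol synthesis genes were lower (adjusted p = 6.83e-05; adjusted p = 0.323 with an estimated correlation): 8 of 18 fell and none rose, and 10 fell and 1 rose adjusted over the list alone. Dhcr7, the last enzyme of the pathway, fell by 1.57 ± 0.10, Tm7sf2 by 1.25 ± 0.11, Idi1 by 1.15 ± 0.17 and Sqle by 0.62 ± 0.10. Sterol efflux genes and targets of the sterol receptor LXR were higher (adjusted p = 0.00131; adjusted p = 0.482 with an estimated correlation), with 4 of 15 up, and 6 adjusted over the list alone. Lipoprotein lipase Lpl rose by 1.82 ± 0.15, Npc2 by 1.25 ± 0.14, and Abcg5 and Abcg8, which form the sterol pump into bile, by 0.98 ± 0.12 and 0.79 ± 0.10. Bile acid synthesis and transport genes were lower (adjusted p = 0.00159; adjusted p = 0.543 with an estimated correlation), with 6 of 21 down and the transporter Slco1a4 up (0.50), the same counts as adjusted over the list alone. Cyp7b1 fell by 1.94 ± 0.09, Slco1a1 by 1.77 ± 0.19, the bile acid importer Slc10a1 by 1.12 ± 0.22, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by 0.47 ± 0.10.

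Genes of fatty acid oxidation and targets of the fatty acid receptor PPAR alpha were lower (adjusted p = 4.99e-06; adjusted p = 0.543 with an estimated correlation), with 5 of 31 down, and 6 adjusted over the list alone. The microsomal hydroxylases Cyp4a14, Cyp4a31 and Cyp4a10 fell by 1.31, 1.14 and 0.93. The list median was 0.06 on the atherogenic high-fat 6-week array and between -0.70 and -0.39 on the others. Genes with higher expression in male than female liver were lower (adjusted p = 4.18e-09; adjusted p = 0.212 with an estimated correlation): 8 of 15 fell, and 11 adjusted over the list alone, including Elovl3, Cyp7b1, Slco1a1 and Cyp4a12a (-1.09 ± 0.09). Xenobiotic metabolism genes (adjusted p = 0.0338; adjusted p = 0.601 with an estimated correlation) had 7 of 41 down, among them Cyp2c50 and Ces3a at -1.14 each, and 2 up, Cyp2a5 and Cyp2c55; adjusted over the list alone, 7 fell and 3 rose. The list median was -0.57 and -0.27 on the plain arrays and 0.05 and 0.07 on the high-fat arrays. Hepatocyte markers (adjusted p = 0.013; adjusted p = 0.543 with an estimated correlation) had 1 of 30 down, Apoc3 at -0.54, and 1 up, Apoh at 1.09, also adjusted over the list alone. The list median was above 0 on both plain arrays, 0.02 and 0.32. The xenobiotic call ended without the atherogenic 6-week array (adjusted p = 0.344) or the atherogenic 24-week array (0.0812), and the hepatocyte call without the atherogenic high-fat 6-week array (0.133).

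Ribosomal protein genes had the smallest p of the 31 lists (adjusted p = 2.79e-14; adjusted p = 0.482 with an estimated correlation): 23 of 52 rose, led by Rpl32 at 1.11 ± 0.14 and Rps12 at 1.01 ± 0.13, and 40 adjusted over the list alone. Of the 14 lists that were not called, some held members that passed. In the antioxidant and glutathione list (adjusted p = 0.134; 5 of 46 up and 2 down, 10 and 4 adjusted over the list alone) Gsta2 rose by 1.70 ± 0.21 and Gsta1 by 1.49 ± 0.17, while catalase, Cat, fell by 0.57 ± 0.09. Sod1 at -0.33, Sod2 at -0.13 and Gpx1 at -0.10 did not pass. Gpx1 stood at 0.87 and 0.59 with the plain diet and at -1.14 and -0.71 with high fat. Its probe lay at a value shared by many probes on the atherogenic 24-week array, so the size of this difference between diets cannot be read. In the list of NADPH oxidase subunits (adjusted p = 0.346; 3 of 6 up and 1 down, also adjusted over the list alone) Cybb rose by 1.05 ± 0.21 and Cyba by 0.63 ± 0.09, with the 2 probes of Cyba at -0.40 and 1.66. In the lipid uptake list (adjusted p = 0.991; 2 of 21 up and 2 down, 5 and 4 adjusted over the list alone) Fabp5 rose by 1.38 and the fatty acid receptor Cd36 by 0.88. Scd1 rose by 0.89 ± 0.17 and Dgat1 fell by 1.16 in the fatty acid synthesis list (adjusted p = 0.371; 1 of 23 up and 3 down, 4 and 4 adjusted over the list alone). Fasn, at 0.29 ± 0.08, did not pass, but did with its single larger probe (0.62). The mean of Dgat1 came from probes at -2.25 and -0.06.

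On single arrays, which have no test, 5 lists lay above the 97.5th percentile of 10000 random lists of their size on all 4 arrays and 2 lay below the 2.5th. Median log2 ratios of macrophage markers were 0.85 and 0.80 with the atherogenic diet at 6 and 24 weeks and 0.52 and 0.34 with the added high fat. Male-biased genes had medians between -0.87 and -0.68. MHC class II genes had medians between 0.55 and 1.23.

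**Figure D2:**
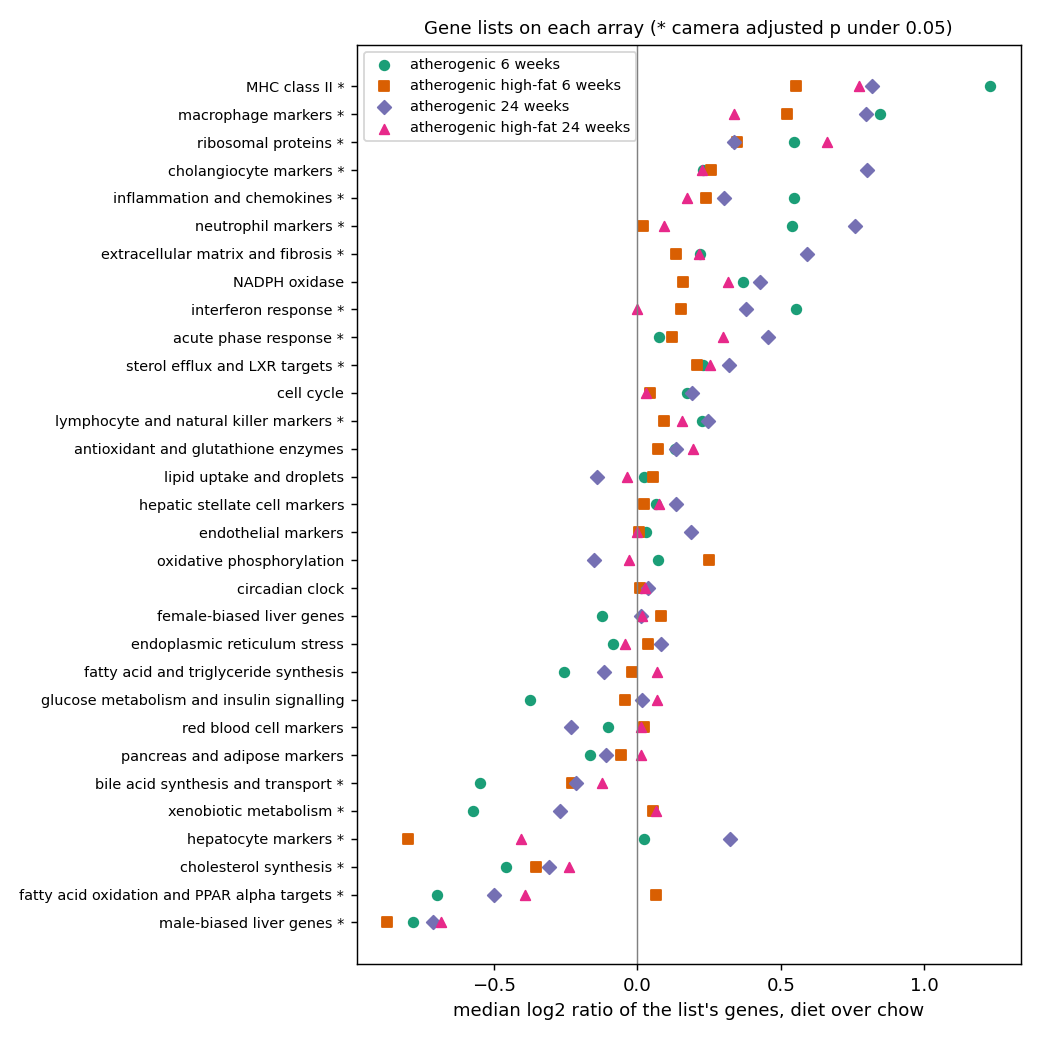
Median log2 ratio of diet over chow (horizontal axis) of the measured genes of each of the 31 lists, with a point for each array; a star marks a camera adjusted p under 0.05 over the 4 arrays together. Male-biased genes lie between -0.87 and -0.68 on all 4 arrays, while hepatocyte markers lie at 0.02 and 0.32 on the atherogenic arrays and at -0.80 and -0.41 on the high-fat arrays.

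Counts by size describe each array without a test. At least 2-fold differences from chow were found for 1699 probes with the atherogenic diet at 6 weeks (1122 higher, 577 lower) and 1024 at 24 weeks (539 higher, 485 lower). With the added high fat they numbered 639 at 6 weeks (223 higher, 416 lower) and 784 at 24 weeks (290 higher, 494 lower). Across all 4 arrays 219 probes differed at least 2-fold in 1 direction, 85 higher and 134 lower, where independent arrays with these counts would give 0.00181 and 0.00266. Simulated unchanged probes, with equal noise in diet and chow samples, gave means of 0.22 and 0.29 with chow shared within each duration. With chow shared by all 4 arrays the means were 8.64 and 11.1. No dye bias was simulated. If the deposited values were natural logarithms the 219 would be 7, and with base 2 it would be 0. After scaling each array to a common spread the counts per array were 736, 1152, 758 and 1360 in the order atherogenic 6 weeks, atherogenic high-fat 6 weeks, atherogenic 24 weeks and atherogenic high-fat 24 weeks.

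The second comparison asks what the added high fat changed. The difference is the mean of high-fat minus plain atherogenic values within each duration. Cyp2b9, a drug-metabolising cytochrome, was higher by 1.69 ± 0.25 (adjusted p = 0.0201), and Cyp8b1 by 1.61 ± 0.29, standing at -4.33 and -3.42 with the plain diet and at -2.04 and -2.49 with high fat; with arrays scaled to a common spread its difference was 0.29 and did not pass. Car3, a carbonic anhydrase of liver and fat, was higher by 1.53 ± 0.14, Thrsp, a gene induced during fatty acid synthesis, by 1.52 ± 0.22, and the carboxylesterase Ces1d by 1.41 ± 0.26. Rims2, Ovol2 and Ctdnep1 were higher by 1.51, 1.48 and 1.38. The 8 genes named by the rule for lower values were Mrgpra4 (-2.24 ± 0.32), Serpina1a (-2.02), Mgst1 (-2.02), Serpina1b (-2.0), B3gnt4 (-1.92), Apoe (-1.90), Chst12 (-1.83) and Agbl3 (-1.82). Serpina1a and Serpina1b encode secreted protease inhibitors made in hepatocytes and are near-identical copies. Of these 8, Serpina1a, Serpina1b, Mgst1, B3gnt4, Apoe and Agbl3 had probes within 0.003 (log10) of a value shared by many probes on the atherogenic 24-week array, as did Gpx1 (-1.66 ± 0.19), so the size of these differences cannot be read. Serpina1b also had such values on both high-fat arrays. In a narrower window at the shared value of the atherogenic 24-week array lay 132 probes, where the surrounding values would give 84.8. Many probes there therefore belong to the ordinary spread of values.

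In limma 4411 probes passed an adjusted p of 0.05, 2440 higher and 1971 lower with high fat, and 10244 had an unadjusted p under 0.05. With each array centred on its median the split was 1380 higher and 1683 lower, with arrays also scaled 2423 and 3020, with centring by the position in the probe identifiers 1992 and 2495, and over genes 504 higher and 962 lower. This fit has 1 residual degree of freedom for each probe. Without a duration term 740 probes passed, and leaving out, also without that term, the atherogenic 6-week, the atherogenic high-fat 6-week or the atherogenic high-fat 24-week array left 0.

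Xenobiotic metabolism genes were higher with high fat (adjusted p = 7.44e-07; adjusted p = 0.756 with an estimated correlation): 12 of 41 rose and 2 fell, and 17 and 3 adjusted over the list alone. In this and the next paragraph, list members outside the naming rule were chosen after their values were seen. Cyp2c39 was higher by 1.11, Cyp1a2 by 1.10, Cyp3a25 and Cyp2c50 by 1.03, and Cyp3a11 (-0.99) and Sult1d1 (-0.84) were lower. Oxidative phosphorylation genes were higher (adjusted p = 0.000116; adjusted p = 0.756 with an estimated correlation), with 3 of 63 up, Uqcrfs1 (0.95), Cox6c (0.73) and Ndufa6 (0.69), and 0 adjusted over the list alone. Fatty acid oxidation genes (adjusted p = 0.00075; adjusted p = 0.756 with an estimated correlation) had 6 of 31 up, led by Eci2 at 1.07, and 3 down, Fabp1 (-1.24), Acot2 (-0.66) and Ppargc1a (-0.65); adjusted over the list alone, 8 rose and 3 fell, and the list median was 0.58 at 6 weeks and 0.10 at 24 weeks. Fatty acid and triglyceride synthesis genes (adjusted p = 0.00101; adjusted p = 0.756 with an estimated correlation) had 3 of 23 up, Thrsp, Scd2 (1.04) and Fads2 (0.89), and 7 adjusted over the list alone. Bile acid genes (adjusted p = 0.00191; adjusted p = 0.756 with an estimated correlation) had 3 of 21 up, Cyp8b1, Slc10a1 (1.02) and Slc27a5 (1.01), as adjusted over the list alone. Ribosomal protein genes (adjusted p = 0.0351; adjusted p = 0.757 with an estimated correlation) had 2 of 52 up, Rpl23 (0.74) and Rpl21 (0.59), and 1 adjusted over the list alone; the list median was -0.14 at 6 weeks and 0.33 at 24 weeks. Glucose metabolism genes (adjusted p = 0.0442; adjusted p = 0.756 with an estimated correlation) had 2 of 25 up, Pfkfb3 (0.98) and Pck1 (0.96), as adjusted over the list alone, with a list median of 0.19 at 6 weeks and 0.01 at 24 weeks.

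Hepatocyte markers were lower with high fat (adjusted p = 0.00135; adjusted p = 0.756 with an estimated correlation): 16 of 30 fell and 2 rose, Serpina6 (1.10) and F2 (0.62), and 17 and 5 adjusted over the list alone. Ttr stood at -1.81, Rbp4 at -1.68, Trf at -1.57 and Alb at -1.53. Of the 37 probes of this list, 12 lay at the shared value of the atherogenic 24-week array, and without all probes at such values, a removal that picks probes by their ratio, the list was no longer called (adjusted p = 0.253). Macrophage markers were lower (adjusted p = 0.00443; adjusted p = 0.756 with an estimated correlation), with 7 of 32 down, led by Vsig4 (-1.18) and Itgax (-0.83), and 9 adjusted over the list alone. After scaling, the macrophage direction turned to higher (adjusted p = 0.648). Interferon response genes were lower (adjusted p = 0.00191; adjusted p = 0.756 with an estimated correlation): 7 of 25 fell, led by Gbp3 at -1.31, and 10 adjusted over the list alone. Neutrophil markers were lower (adjusted p = 0.0488; adjusted p = 0.756 with an estimated correlation), with 4 of 12 down, Ngp (-1.05), Camp (-0.95), Chil3 (-0.91) and Csf3r (-0.68), and 6 adjusted over the list alone; the list median was -0.63 at 6 weeks and -0.13 at 24 weeks. With arrays scaled the neutrophil, bile acid, fatty acid oxidation and glucose calls ended (adjusted p = 0.382, 0.128, 0.128 and 0.133). The neutrophil and glucose calls also ended with camera on ranks (0.055 and 0.053), the neutrophil call without probes at repeated values (0.099) and the glucose call with centring by position (0.114). The 20 other lists were not called; among them the median, mean and test differed in sign for acute phase, stellate cell, endoplasmic reticulum stress, male-biased and circadian genes.

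**Figure D3:**
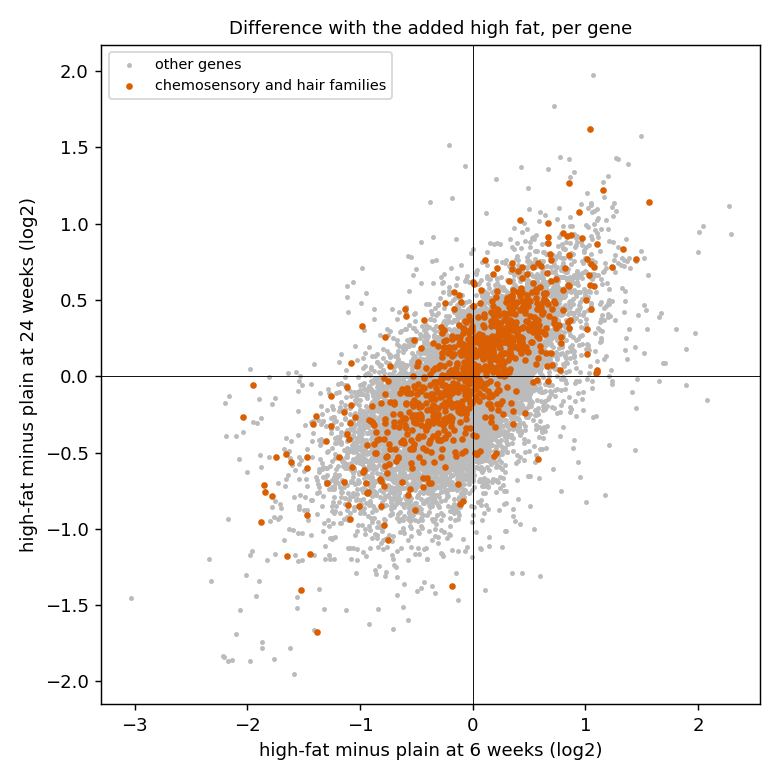
Difference in log2 ratio between the high-fat and the plain atherogenic array at 6 weeks (horizontal axis) and at 24 weeks (vertical axis), with a point for each gene; genes of chemosensory receptor and hair keratin-associated families are coloured. The correlation across genes is 0.75 in these families and 0.63 in the other genes.

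The third comparison asks what changed between 6 and 24 weeks, as the mean of 24 minus 6 weeks within each diet. No probe passed an adjusted p of 0.05 in limma (smallest 0.147), while 2655 had an unadjusted p under 0.05 where independent arrays without change would give 1394. The following genes are therefore values only. The genes named by the rule for lower values at 24 weeks were Cxcl9 at -1.99, Marco, a scavenger receptor of macrophages, at -1.78, Tgtp1 at -1.42, Ccl8 at -1.28, Fabp2 at -1.27, Ccl2 at -1.22, G0s2 at -1.11 and Acot1 at -1.08. Ccl2 stood at 1.67 and 1.57 at 6 weeks and at 0.44 and 0.36 at 24 weeks. Those named for higher values were Mt1, a metal-binding protein, at 1.38, Marchf9 at 1.32, Hsd3b4 and Kcnk13 at 1.16, Olfr859 at 1.02, Mug2 at 1.01, Zfyve26 at 0.94 and Ddx52 at 0.92. Col1a2 stood at 0.75 and 2.35 with the plain diet and at 1.82 and 2.08 with high fat. Tgfb1 differed by 0.86 (adjusted p = 0.176).

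By list, extracellular matrix genes were higher at 24 weeks (adjusted p = 5.75e-08; adjusted p = 0.775 with an estimated correlation), with 44 of 51 differences above 0, a median of 0.24 and 3 members past the threshold adjusted over the list alone; the median was 0.41 in the plain diet and 0.09 with high fat. Bile duct cell markers (adjusted p = 2.24e-05; adjusted p = 0.775 with an estimated correlation) had 13 of 14 above 0 and 4 past it. Acute phase genes (adjusted p = 7.59e-05; adjusted p = 0.752 with an estimated correlation) had a median of 0.32, with 7 higher and 1 lower adjusted over the list alone. Also higher were the hepatocyte (adjusted p = 9.05e-05; median 0.18), xenobiotic (0.000181; 0.21), antioxidant (0.0101; 0.09), fatty acid synthesis (0.0159; 0.13) and neutrophil lists (0.0174; 0.16), each with adjusted p = 0.752 with an estimated correlation. The bile acid (0.000376; 0.21) and glucose lists (0.00514; 0.09) were higher with adjusted p = 0.775 with an estimated correlation. In the plain diet and with high fat the xenobiotic medians were 0.38 and 0.02, and the glucose medians 0.33 and 0.06. Oxidative phosphorylation genes were lower (adjusted p = 1.15e-06; adjusted p = 0.752 with an estimated correlation), with a median of -0.19, and 20 of 63 lower and 2 higher adjusted over the list alone. Fatty acid oxidation genes (adjusted p = 3.49e-05; adjusted p = 0.775 with an estimated correlation; median -0.24) were lower, with a median difference of 0.16 in the plain diet and -0.46 with high fat. Lower too were inflammation and chemokine genes (adjusted p = 0.000143; adjusted p = 0.752 with an estimated correlation; median -0.17), of which 7 were lower adjusted over the list alone. The lipid uptake list (adjusted p = 0.00456; adjusted p = 0.752 with an estimated correlation) and the interferon list (adjusted p = 0.0475; adjusted p = 0.775 with an estimated correlation) were lower too, and the interferon call ended with arrays centred (0.0625), scaled (0.145), centred by position (0.0692), without probes at repeated values (0.059) or on ranks (0.135). The antioxidant call ended on ranks (0.0805). The median, mean and test differed in sign for endoplasmic reticulum stress and for pancreas and adipose genes, which were not called. The labels give chow of 24 weeks on both 24-week arrays and of 6 weeks on 1 of the 6-week arrays, so a difference between chow samples can enter these values. With no diet term, leaving out the atherogenic high-fat 6-week array gave 273 probes and leaving out the atherogenic 6-week array 34.

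Arrays of the same diet resembled each other more than arrays of the same duration. Across 27870 probes, which are not independent replicates, Pearson r was 0.73 between the atherogenic arrays and 0.83 between the high-fat arrays. Between diets it was 0.39 at 6 weeks and 0.57 at 24 weeks, and 0.39 and 0.45 for the pairs that shared neither. Simulated unchanged probes had noise of equal size in diet and chow samples. They gave an r of 0.501 with a shared chow sample and 0.000188 with separate ones. The equal noise alone sets these values, so they cannot show whether chow was shared. The covariances were 0.18 and 0.12 within diets and 0.08 and 0.10 within durations. The covariance of 0.0972 simulated with shared chow rests on the same equal noise and on the mean SD of the arrays. Spearman rho within durations was 0.27 and 0.36.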

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

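All tests of explanations in this part were chosen after the results were seen. With 1 array per condition no group was large enough for a search for outlying samples.

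Between high-fat and plain arrays 34 named genes differed past the threshold, 16 of which were named because they passed it. Ratios were narrower on the high-fat arrays, so a gene changed alike in both diets can differ by spread alone. With arrays scaled to a common spread, 15 of these 16 kept their call and Cyp8b1 lost it. The other genes were not repeated with scaling, so this limit stays on their differences. Values are high-fat minus plain (log2). Among genes of metabolism, Cyp2b9 (1.69), Cyp8b1 (1.61), Car3 (1.53), Thrsp (1.52), Ces1d (1.41), Cyp2c50 (1.03), Slc10a1 (1.02), Cd36 (0.73), Fdps (0.71) and Acaa1a (0.62) were higher. Higher too were Rims2 (1.51), Ovol2 (1.48), Ctdnep1 (1.38) and the pancreatic protease Ctrb1 (0.77). Lower were the immune and cell cycle genes Cybb (-0.98), Plk1 (-0.95), Vcam1 (-0.95), Saa3 (-0.89), Ccnb2 (-0.87), Ifi47 (-0.71) and Cd9 (-0.66). Mrgpra4 (-2.24) and Chst12 (-1.83) were lower too. Serpina1a (-2.02), Mgst1 (-2.02), Serpina1b (-2.0), B3gnt4 (-1.92), Apoe (-1.90), Agbl3 (-1.82) and Gpx1 (-1.66) were lower, but had probes at the value shared by many probes on the atherogenic 24-week array, so the size of these differences cannot be read. The remaining lower genes were Clps (-0.85), Kcnk13 (-0.73), Vmn1r179 (-0.65) and Zfyve26 (-0.55).

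Some genes had opposite signs without passing a test of the difference. Saa1 was below chow on both plain arrays and above it on both high-fat arrays (difference 0.33, adjusted p = 0.145). Between 6 and 24 weeks Marco (-1.78) went from above to below chow in both diets, and Mt1 (1.38), Mug2 (1.01) and Olfr859 (1.02) from below to above; no duration difference passed.

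Of the lists called for diet over chow, 8 also differed by high fat at the preset correlation. Their camera adjusted p-values were 7.44e-07 for xenobiotic metabolism, 0.00075 for fatty acid oxidation, 0.00135 for hepatocyte markers, 0.00191 for both bile acid and interferon genes, 0.00443 for macrophage markers, 0.0351 for ribosomal proteins and 0.0488 for neutrophil markers. By duration 10 differed, with 5.75e-08 for extracellular matrix, 2.24e-05 for bile duct cells, 3.49e-05 for fatty acid oxidation, 7.59e-05 for acute phase, 9.05e-05 for hepatocyte markers, 0.000143 for inflammation, 0.000181 for xenobiotic metabolism, 0.000376 for bile acid genes, 0.0174 for neutrophil markers and 0.0475 for interferon response. None passed with an estimated correlation. Ratios were narrower on the high-fat arrays, with a median absolute deviation of 0.27 on each. It was 0.44 and 0.38 on the atherogenic 6-week and 24-week arrays. With arrays scaled to a common spread the high-fat calls of neutrophil, bile acid and fatty acid oxidation genes ended. The macrophage direction turned to higher and was not called.

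Odorant and vomeronasal receptor and hair keratin-associated genes stood among the largest falls. Without the 3 that prompted the test, 80 of 866 genes of these families were called lower. That is 9.24%, against 5.54% of other genes (Fisher's exact test, p = 2.26e-05). Called higher than chow were 17 of all 869 family genes, 1.96%, against 6.56% of other genes (Fisher's exact test, p = 7.91e-10). A bias of probes toward the Cy3 dye could give such falls. If equal in size on all arrays, it would cancel in high-fat minus plain. Of 869 family genes 55, 6.33%, were called higher with high fat, against 3.54% of other genes (Fisher's exact test, p = 0.000125). The share called lower with high fat was 6.67%, against 7.13%. Ratios were narrower on the high-fat arrays (median absolute deviation 0.27 on each, against 0.44 and 0.38 on the plain arrays). A downward bias narrowed in the same way would not cancel and would give such higher calls. The calls were not repeated on scaled arrays, so they cannot decide about a bias shared by all arrays. Such a bias stays open as a part or the whole of the falls. An effect of diet on these genes stays open, as untested. For the rises of immune genes a dye bias stays open too, since no array had the dyes swapped.

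Arrays of 1 diet resembled each other across durations. The high-fat difference at 6 weeks correlated with that at 24 weeks at r = 0.745 in the chemosensory and hair families and at 0.632 in other genes, so part of it may come from array processing that differed between the diets. Differences between position groups read from the probe identifiers are argued against as the whole cause. The r across probes was 0.691 before and 0.674 after centring each group on its median. Position within these groups was not corrected and stays open. An effect of the diet, and processing that differed between the diets, stay open for every gene and list above.

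Hepatocyte markers were lower with high fat. On the atherogenic 24-week array 12 of their 37 probes, 32.4%, lay within 0.003 (log10) of 0.176, against 0.967% of other named probes (Fisher's exact test, p = 1.54e-15), a pile-up that saturated spots could give. Without probes at such repeated values the median difference of the 23 genes left was -0.40 in place of -0.70, and the call ended (adjusted p = 0.253) with fewer members and a smaller difference. This removal picks probes by their ratio, which shrinks the difference by itself, so it decides nothing. Saturation and an effect of diet cannot be told apart for this list, since no intensities were used.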

How the results depend on the processing

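Alternatives that centred by position, removed probes at repeated values or changed the log base were chosen after seeing the data. No analysis paired by animal was possible, because each group has 1 array and replicate numbers pair no animals. The additive model did compare high fat within duration and duration within diet. For diet over chow the count of 2880 probes became 1634 over gene means, 578 with a log2 value of at least 1, 5134 at adjusted p under 0.10, 10181 with diet and duration terms and 9213 with duration as a random block; without each array it ranged from 689 to 2020. For high fat 4411 became 1466 over gene means, 605 with a log2 value of at least 1, 8393 at adjusted p under 0.10 and 740 without a duration term; without each array, and with no duration term, it ranged from 0 to 6194. For duration 0 stayed 0 except without each array, and with no diet term, from 0 to 273. At least 2-fold counts, in the order atherogenic 6 weeks, atherogenic high-fat 6 weeks, atherogenic 24 weeks, atherogenic high-fat 24 weeks and all 4 in 1 direction, were 806, 267, 465, 337 and 87 over genes, 6058, 2218, 4060, 2411 and 711 at 1.5-fold, 330, 174, 294, 247 and 70 at 3-fold, 45, 34, 67, 65 and 7 with base e, and 3, 6, 9, 3 and 0 with base 2. With arrays scaled, they were 736, 1152 and 1360 on the atherogenic 6-week and the high-fat 6-week and 24-week arrays. With an estimated correlation 0 lists were called in each comparison, in place of 17, 11 and 15. That form of the test rests on 3 or 1 residual degrees of freedom, so the loss does not measure correlation between genes alone. The high-fat call of macrophage markers reversed with scaling (adjusted p = 0.648). Spearman rho was 0.27, 0.24, 0.25 and 0.36 between diets (6 weeks, atherogenic 6 with high-fat 24, high-fat 6 with atherogenic 24, 24 weeks) and 0.77 between the high-fat arrays. Counts with centring, scaling, limits on ratios, robust eBayes, position and removal of repeated values stayed within 1.5 times for all 3 comparisons. The cause of these shifts was not tested. No fit for diet over chow allowed for an error shared by arrays of the same diet. The rises to 10181 and 9213 therefore do not show that 2880 is a cautious count. Of the 156 genes named by the rule, 69 lost their diet-over-chow call without the atherogenic 24-week array. Without the atherogenic 6-week, high-fat 24-week and high-fat 6-week arrays 20, 25 and 27 lost it. In the same order of 4 arrays 3, 3, 8 and 8 uncalled genes changed sign. A call was gained by 2 without the atherogenic 6-week and by 1 without the high-fat 6-week array. With arrays centred 1 gene lost its call, and with arrays scaled 1 lost it and 1 uncalled gene changed sign. Signal over background limits every value and is not given here.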

Other observations

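No test in this part was chosen after a result was seen. Cell cycle genes were not called as a list for diet over chow (adjusted p = 0.151), with 6 of 34 up and 2 down, and 7 and 3 adjusted over the list alone: Stmn1 rose by 1.01, Ccnb2 by 0.95 and Mcm6 by 0.52, while the mitotic kinase Plk1 fell by 1.43. Endoplasmic reticulum stress genes (adjusted p = 0.991) held 2 rises among 24, Pdia3 at 0.58 and Ddit3 at 0.41, also adjusted over the list alone; the test of the list and its median differed in sign, as for circadian genes. In the glucose and insulin list (adjusted p = 0.278; 3 of 25 down, and 4 down and 2 up adjusted over the list alone) Igf1 fell by 0.64, G6pc by 0.59 and Irs2 by 0.39. Of the oxidative phosphorylation list (adjusted p = 0.484; 2 of 63 up, and 0 adjusted over the list alone) Atp5pb rose by 0.48 and Ndufa2 by 0.42. Per1 fell by 0.52 in the circadian list (adjusted p = 0.991), and the endothelial gene Vwf rose by 0.34 (list adjusted p = 0.346; 1 of 20 up, and 0 adjusted over the list alone).

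Female-biased liver genes did not mirror the fall of male-biased genes: 0 of 11 rose or fell for diet over chow, and the list was not called (adjusted p = 0.881). Red blood cell markers (adjusted p = 0.347) and pancreas and adipose markers (adjusted p = 0.371) had no member past the threshold. For these Slc4a1 stood at 0.11, Clps at 0.47 and Ctrb1 at -0.49.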
